A study of Homo sapiens with 4 samples.

How the data were processed

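The series holds 4 RNA-seq libraries of HepG2 cells, 2 per group, and 2 tables that cover all of them with the same genes in the same order. The authors deposited raw read counts per gene, whole numbers without normalization, and FPKM per gene, per the file headers. Aligner, counting tool, genome build, annotation, library kit and the use of strand are not given in the sources used here. Groups came from the sample titles, and so did the numbers used here as replicate numbers. The titles do not say whether a number stands for a replicate or a hairpin. Columns were matched to samples by names: the Ctrl columns give cell line, Ctrl and number, while the other 2 give cell line, "Si" and number, which the labels do not explain and which was inferred to stand for STAT3 shRNA. Of 27452 genes, 26420 had a versioned Ensembl ID and 1032 an ID outside Ensembl, which took 0.741% to 0.834% of reads. Gene symbols came from the tables. Of the Ensembl IDs 25996 were found in GENCODE 29 without their version and 16310 with the same version, so positions, transcript lengths and GC content (longest transcript) are from that annotation and not from the one used by the authors.

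Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors 0.979, 0.951, 1.03 and 1.04; filterByExpr with default settings, which kept 15199 genes; glmQLFit and glmQLFTest, two-sided, group as the only term), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The common dispersion was 0.00967, a coefficient of variation of 0.0984. CPM are TMM-scaled, errors of CPM are SDs over 2 libraries, and errors of log2 fold changes are SEs from the quasi-likelihood F. A gene at 0 in both libraries of a group is given as a bound against 3 reads over that group (0.079 CPM for Ctrl shRNA and 0.0666 CPM for STAT3 shRNA). Floors and counting intervals (exact binomial, 95%) cover counting error only, since reads without molecular identifiers are not independent molecules.

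Gene lists (42, with 1201 genes, 917 of them tested) were written before the data were examined and cover liver functions, STAT3 and cytokine signalling, metabolism, stress, proliferation and markers of other cell types. Lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided, adjusted over 40 lists), and with an estimated correlation and fry as alternatives. Members at 0 in a group, present in 4 lists, were also set to their bound, which changed 0 of the medians. Named genes followed a rule fixed beforehand: STAT3; the 10 largest rises and 10 largest falls by log2 fold change among changed genes without overlap between groups, with at least 5 CPM in the higher group and without clone-type names; the 3 smallest p-values of each list that passed the set test or had at least 3 changed members; the 2 most abundant markers of other cell types; and the other STAT genes. STAT4 did not pass the filter. Values of some genes that this rule names are not reported here.

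Near-identical copies of the 129 named genes were sought with blastn 2.17.0 among GENCODE 29 transcripts (at least 95% identity over at least 50% of the longest transcript), and reads were summed over a gene and its copies. Overlapping genes were listed as well: 54 of the named genes share a span with another gene that has reads, and for 23 of them that gene holds at least 20% as many reads, among them FOSB, SLC16A3, NDUFA1, NDUFB3, TGM2, COL4A1, CLDN7, BCL2L11, IFITM1, PC, PRIM1, RNF43 and STAT6. Their values are uncertain to that extent, since strand is not stated. Identity lists of 14 tissues, of which the hepatocyte identity list is used below, were written after a first look at the data, when the largest changes (FOLH1 among them) had been seen but not the levels of the lists.

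Alternatives planned beforehand were RLE and upper-quartile scaling, no low-count filter, a filter of 5 CPM in 2 libraries, the replicate number as a block, leaving out each library, DESeq2 1.42.0, the edgeR exact test, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), a threshold of 0.01 and a test against a fold of 1.5. Offsets for transcript length and for GC content (lowess per library) and the sums over copies were added after the data were seen. Median log2 fold changes of 50 consecutive genes were set against 1000 shuffled gene orders.

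Counts were simulated for 15199 independent genes with the means and depths of this comparison and its common dispersion for every gene. On them the edgeR test recovered 23 of 50 genes changed 1.5-fold and 42 of 50 changed 2-fold. Of those changed 4-fold and 8-fold it recovered 50 of 50 and 49 of 50, and it called 4 of 14999 unchanged genes. Spread that differs by gene or group, GC trends and correlation among genes were not simulated, so these rates may not hold for the data. Of 5 lists lowered by 0.4 on the log2 scale camera called 5 with the preset correlation and 0 with an estimated one, with 0 calls among the others. The scan along chromosomes found a shifted block of 100 genes in 20 of 20 runs and did not pass its threshold in 16 of 20 shuffled orders. Lists drawn at random fell at or under the 2.5th percentile of matched lists in 1 of 20 runs, and lists shifted by -0.35 in 20 of 20. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.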

Results

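RNA sequencing compared gene expression in HepG2 cells, an established human hepatoma line, after a short hairpin RNA against STAT3 (STAT3 shRNA) or a control hairpin (Ctrl shRNA). The comparison asked how lowering STAT3, a transcription factor activated by cytokine and growth factor receptors, changed the expression of other genes. Each group had 2 libraries. The tables held read counts and FPKM for 27452 genes. Total counts were 19283150 and 20133064 in the Ctrl shRNA libraries and 25862027 and 17694642 in the STAT3 shRNA libraries, so 3 reads corresponded to 0.116 to 0.170 CPM (counts scaled to library size) in a single library. Correlations of log2(CPM + 1) across genes were 0.991 between the Ctrl shRNA libraries and 0.9951 between the STAT3 shRNA libraries, against 0.965 to 0.9727 between libraries of different groups. Counts of 2 libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 14.6 for Ctrl shRNA and 4.34 for STAT3 shRNA, so neither pair is 1 library deposited 2 times. Nothing in the labels says that the libraries of a group came from separate cultures, or whether they share a hairpin. The p-values therefore measure the spread between these libraries, which may be technical. Effects of a hairpin other than on STAT3 were not separated.

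STAT3 itself (ENSG00000168610.14; chromosome 17, 42313324 to 42388568, minus strand) was read first, as a check of the labels. It was at 245.03 and 244.3 CPM in the Ctrl shRNA libraries and at 34.7 and 36.1 CPM in the STAT3 shRNA libraries, means of 244.7 ± 0.504 and 35.4 ± 0.954 CPM (SD, n = 2 each). The log2 fold change was -2.79 ± 0.09 (SE; 95% interval -2.98 to -2.59), a 6.91-fold fall with an adjusted p of 3.28e-07 (edgeR quasi-likelihood test, two-sided, Benjamini-Hochberg). Values of 4 other STAT genes lay closer together in the groups. STAT2 had a log2 fold change of -0.19 (adjusted p = 0.196 in the edgeR test), STAT5A -0.10 (0.415) and STAT5B -0.07 (0.587), and none of these passed. STAT6 fell by 0.28 on the log2 scale in the edgeR test (adjusted p = 0.0355), a call that was lost when either STAT3 shRNA library was left out (0.188 and 0.299), with upper-quartile scaling, with a GC offset and with FPKM (range over its alternatives 0.000634 to 0.299). Reads of STAT6 cannot be separated from those of the opposite-strand gene LRP1 where strand was not used.

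**Figure D1:**
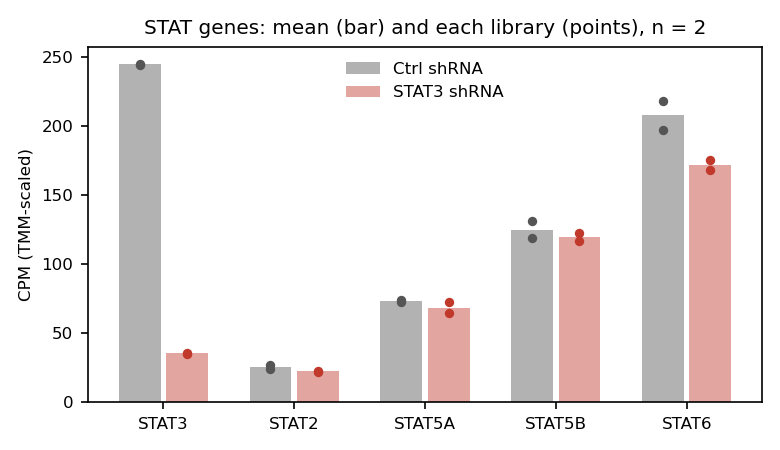
CPM (vertical axis, TMM-scaled) of STAT3 and 4 other STAT genes in Ctrl shRNA (grey) and STAT3 shRNA (red) libraries; bars are group means and points the 2 libraries of each group. STAT3 was at 244.7 CPM against 35.4 CPM, while the log2 fold changes of those 4 genes lay between -0.28 and -0.07.

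Expression differed between the groups well beyond STAT3. Of 15199 genes tested, 5396 (35.5%) changed at an adjusted p under 0.05 in the edgeR quasi-likelihood test, 2552 higher and 2844 lower with STAT3 shRNA. Changes of at least 2-fold were fewer, 765 higher and 548 lower. The changed genes comprised 4811 protein-coding genes, 124 pseudogenes, 163 loci without an Ensembl ID and 298 others. CPM of the groups did not overlap in 5395 of the 5396 changed genes and in 10755 of all tested genes, where chance gives 33.3% for 2 libraries against 2. The counts of calls depended on which library was left out. Without a STAT3 shRNA library the spread came from the Ctrl shRNA pair alone, and fewer genes were called. That pair varied more, with a chi-square per degree of freedom of 14.6 against 4.34 for the STAT3 shRNA pair. Without a Ctrl shRNA library more genes were called. With the deposited FPKM and limma-trend in place of counts, at 1 or both pseudocounts, the calls of STAT6, AHSA1, BCL2L11, C3, FAP, FN1, FTH1, H19, MT-CO1, MT-CO2, MT-CYB, MT-RNR2, NCL, PFKL, PPARGC1A, RNF43, RRM2 and TENM3 were lost. Log2 fold changes fell with the GC content of a gene's transcript (Spearman rho -0.339 across genes, which are not independent replicates), and the Ctrl shRNA libraries differed from each other along GC content as well (rho 0.473).

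Among genes with clear names, the 10 largest rises included FOLH1, a glutamate carboxypeptidase also known as prostate-specific membrane antigen, which went from 0.158 ± 0.00158 to 16.8 ± 0.930 CPM (SD, n = 2 each; log2 fold change 6.68 ± 0.27). DPYSL3, a cytoskeletal phosphoprotein of neurons, rose from 2.79 ± 0.102 to 162.0 ± 0.516 CPM, a 57.9-fold change and the most abundant protein-coding gene of this group that has no near-identical copy. PAGE1, a cancer-testis antigen, rose from 3.13 ± 0.676 to 107.3 ± 0.631 CPM (34.2-fold), and KRT4, a keratin of mucosal epithelium, from 1.39 ± 0.321 to 52.4 ± 0.745 CPM (37.4-fold). FMOD, a collagen-binding proteoglycan, reached 8.12 CPM from 0.105 CPM, NMNAT2, an enzyme of NAD synthesis, 5.69 CPM from 0.132 CPM, and BAIAP2L2, a membrane-bending protein, 5.88 CPM from 0.184 CPM. PELI2, a Pellino ubiquitin ligase, had 3 reads in the Ctrl shRNA libraries against 346 in the STAT3 shRNA libraries, a ratio of 97.2 with a 95% counting interval of 33.0 to 473.8. NMNAT2 had a log2 fold change of 5.36, which was 6.58 without Ctrl shRNA replicate 1 and 4.69 without replicate 2. These 8 genes had adjusted p-values of 2.25e-08 to 0.000123 (edgeR) and were higher in both STAT3 shRNA libraries than in either Ctrl shRNA library. The remaining 2, PWP2 and EIF3CL, have near-identical copies. Their log2 fold changes of 6.79 and 4.92 became -0.66 and -0.16 when reads of FP565260.1 and of EIF3C were added, so the rises of PWP2 and EIF3CL are uncertain.

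Among the 10 largest falls, SLC12A3, the thiazide-sensitive sodium-chloride cotransporter, went from 368.0 ± 3.78 to 1.73 ± 0.525 CPM (SD, n = 2 each; log2 fold change -7.68 ± 0.15, 205.3-fold). ALPI, intestinal alkaline phosphatase, fell from 1227 ± 257.5 to 7.22 ± 1.14 CPM (167.9-fold). It lies in the lower segment of chromosome 2, beside the related genes ALPP (5100 to 3531 CPM) and ALPG (31.7 to 9.04 CPM). WFDC1, a secreted WAP-domain protein, fell 44.2-fold from 41.5 CPM, and TENM3, a teneurin adhesion protein, 43.1-fold from 7.05 CPM. BCAT1, the cytosolic branched-chain aminotransferase, fell 28.1-fold from 7.04 CPM. SLC2A3, the glucose transporter GLUT3, fell from 5.78 to 0.0750 CPM, with 4 reads in one STAT3 shRNA library and 0 in the other. FAM220A had 482 and 194 reads in the Ctrl shRNA libraries and 0 in both STAT3 shRNA libraries, at least 268.1-fold lower against a floor of 3 reads over the group (152.3-fold without Ctrl shRNA replicate 1 and 383.8-fold without replicate 2). MT-RNR2, the 16S mitochondrial ribosomal RNA, was at 1.43 and 8.78 CPM in the Ctrl shRNA libraries and fell to 0.146 CPM. It had 27 and 168 reads in the Ctrl shRNA libraries and 2 and 4 in the STAT3 shRNA libraries. The mitochondrial messenger RNA MT-CO1 was at 8105 CPM in Ctrl shRNA. With so few reads of a ribosomal RNA and a library kit that is not given, the fall of MT-RNR2 is uncertain as a change of expression. The pseudogene ZBTB45P2, with 77 and 276 reads in the Ctrl shRNA libraries and 0 in both STAT3 shRNA libraries, was at least 139.0-fold lower (216.7-fold without Ctrl shRNA replicate 1 and 61.3-fold without replicate 2), while its sum with the copy ZBTB45P1 fell by 1.57 on the log2 scale. NPY4R2 fell by 6.10 alone, and its sum with the copy NPY4R, a neuropeptide Y receptor, fell by 2.31. With 1 library left out, log2 fold changes ran from -6.00 to -3.35 for MT-RNR2 and from -6.45 to -4.66 for TENM3, and SLC2A3 was at -5.22 without STAT3 shRNA replicate 2. Without replicate 1, SLC2A3 had 0 reads left in that group, so the fitted -9.77 depends on the prior count and is no bound. The 10 adjusted p-values in the edgeR test ran from 2.25e-08 to 0.00376.

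Of 42 gene lists fixed before the data were examined, 40 had at least 5 tested members, and 12 differed from the other genes in the camera set test with a preset correlation of 0.01, 8 lower and 4 higher with STAT3 shRNA. Counts below are of tested members. With an estimated correlation none of the 12 passed, each with an adjusted p = 0.666 (camera). That form of the test also called 0 of 5 simulated lists that were shifted, so its lack of calls decides little. The directional fry test called 2 lists, both higher: NF-kB and inflammatory genes (adjusted p = 0.0255) and Wnt/beta-catenin targets (adjusted p = 0.0255). With fry 39 of the 40 lists held members changed in either direction. That form of fry does not set a list against other genes, and 35.5% of all tested genes changed.

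Ribosomal proteins, nuclear-encoded oxidative phosphorylation and ribosome biogenesis were called lower with STAT3 shRNA. Of 74 cytosolic ribosomal proteins, 60 fell, 0 rose and 14 did not pass, with a median log2 fold change of -0.53 (camera adjusted p = 2.59e-16, preset correlation; 65 fell when adjusted over the list alone). RPS29 went from 287.1 ± 17.6 to 142.4 ± 3.34 CPM (SD, n = 2 each), RPS3 from 1607 ± 127.8 to 896.9 ± 28.5 CPM, and RPL37A, in the lower segment of chromosome 2, from 875.9 to 321.6 CPM. Reads of the whole list made up 6.99% and 8.21% of the Ctrl shRNA libraries and 5.71% and 5.86% of the STAT3 shRNA libraries. Nuclear-encoded subunits of oxidative phosphorylation had 38 of 51 lower and 0 higher (40 lower when adjusted over the list alone), a median of -0.43 and a camera adjusted p of 4.49e-11. NDUFA1, a complex I subunit, fell by 1.54 on the log2 scale, and the complex I subunits NDUFA10 and NDUFB3, both in the lower segment of chromosome 2, fell by 1.01 and 1.08. Ribosome biogenesis genes and MYC targets had 16 lower and 2 higher of 32 (18 and 2 adjusted over the list alone; median -0.27, camera adjusted p = 0.0022). BOP1 and RRS1, both needed to make the large ribosomal subunit, fell by 0.91 and 0.70, and nucleolin (NCL, in the same segment of chromosome 2) fell by 0.62.

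The lists of cholesterol synthesis, glycolysis and hypoxia were called lower as well. Cholesterol synthesis and uptake had 18 lower and 2 higher of 25 members (19 and 2 adjusted over the list alone; median -0.52, camera adjusted p = 1.11e-07). Mevalonate diphosphate decarboxylase (MVD) went from 70.1 ± 11.6 to 26.6 ± 1.14 CPM, farnesyl diphosphate synthase (FDPS) from 496.9 ± 56.0 to 276.0 ± 1.86 CPM, and DHCR7, the last enzyme of cholesterol synthesis, from 222.5 ± 10.4 to 131.9 ± 3.11 CPM (SD, n = 2 each). In glycolysis 15 of 25 genes were lower and 1 higher (19 and 1 adjusted over the list alone; median -0.37, camera adjusted p = 5.96e-06). The lactate exporter SLC16A3 fell from 532.1 to 179.9 CPM, and the liver-type phosphofructokinase PFKL from 273.0 to 142.7 CPM, although the deposited FPKM of PFKL gave a log2 fold change of -0.01. Hypoxia and angiogenesis genes had 12 lower and 2 higher of 30, also when adjusted over the list alone (median -0.31, camera adjusted p = 0.000209). EPAS1, the hypoxia-inducible factor HIF-2 alpha, fell 6.81-fold from 46.5 to 6.78 CPM, BHLHE40, a hypoxia-induced repressor, 2.43-fold, and DDIT4, an inhibitor of mTOR signalling, 2.17-fold.

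Of 28 listed STAT3 target genes, STAT3 itself not among them, 26 were tested, and of these 14 fell, 3 rose and 9 did not pass (15 and 3 adjusted over the list alone), with a median of -0.40 and a camera adjusted p of 0.00012. The mucin MUC1 went from 172.3 ± 15.3 to 36.4 ± 0.826 CPM, nicotinamide N-methyltransferase (NNMT) from 185.5 ± 2.39 to 81.5 ± 4.06 CPM, and the transcription factor CEBPD from 75.6 ± 7.77 to 31.6 ± 0.187 CPM (SD, n = 2 each). Heat shock proteins had 8 lower and 2 higher of 20, also when adjusted over the list alone (median -0.06, camera adjusted p = 0.0409). HSPE1 and HSPD1, the mitochondrial chaperonins, lie head to head in the lower segment of chromosome 2 with overlapping spans, and fell by 1.40 and 0.74. AHSA1, a co-chaperone of HSP90, fell by 0.68 in counts but had a log2 fold change of 0.0017 in the deposited FPKM. The heat shock call was lost in 8 of 13 alternatives, among them without Ctrl shRNA replicate 1 (adjusted p = 0.145), where the median turned to 0.030, and without STAT3 shRNA replicate 2 (0.184), and ran from 0.00213 to 0.666 over its alternatives.

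The 4 lists called higher with STAT3 shRNA were inflammatory genes, YAP/TAZ targets, cell cycle genes and immediate-early genes. In the NF-kB and inflammatory list 6 of 17 genes rose and 1 fell (7 and 1 adjusted over the list alone; median 0.23, camera adjusted p = 5.29e-05). The cytokine IL32 rose from 10.8 ± 0.413 to 58.7 ± 1.89 CPM, cyclooxygenase 2 (PTGS2) from 7.50 ± 0.111 to 47.7 ± 6.57 CPM, and lipocalin 2 (LCN2) from 2.58 ± 0.175 to 16.0 ± 1.54 CPM (SD, n = 2 each). Of 20 targets of YAP/TAZ, the coactivators of the Hippo pathway, 12 rose and 0 fell (13 and 0 adjusted over the list alone; median 0.43, camera adjusted p = 0.000214), among them ASAP1 (1.75-fold), AMOTL1 (1.55-fold) and the receptor kinase AXL (1.51-fold). Cell cycle and mitosis genes had 19 higher and 2 lower of 48 (21 and 2 adjusted over the list alone; median 0.19, camera adjusted p = 0.00222). NUSAP1, a spindle protein, rose from 158.9 to 344.7 CPM and HMMR from 47.2 to 79.5 CPM, and RRM2, a subunit of ribonucleotide reductase in the higher segment of chromosome 2, from 294.5 to 466.5 CPM. Immediate-early genes had 9 higher and 6 lower of 32 (11 and 6 adjusted over the list alone; median 0.24, camera adjusted p = 0.0409). FOSB rose 4.87-fold from 17.6 to 85.8 CPM, on a span shared with the opposite-strand gene ERCC1, and FOS rose 1.87-fold, whereas NR4A2, in the lower segment of chromosome 2, fell 2.61-fold. Without Ctrl shRNA replicate 1 or STAT3 shRNA replicate 2 the immediate-early call was lost (adjusted p = 0.246 and 0.152; range over its alternatives 0.00141 to 0.666).

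**Figure D2:**
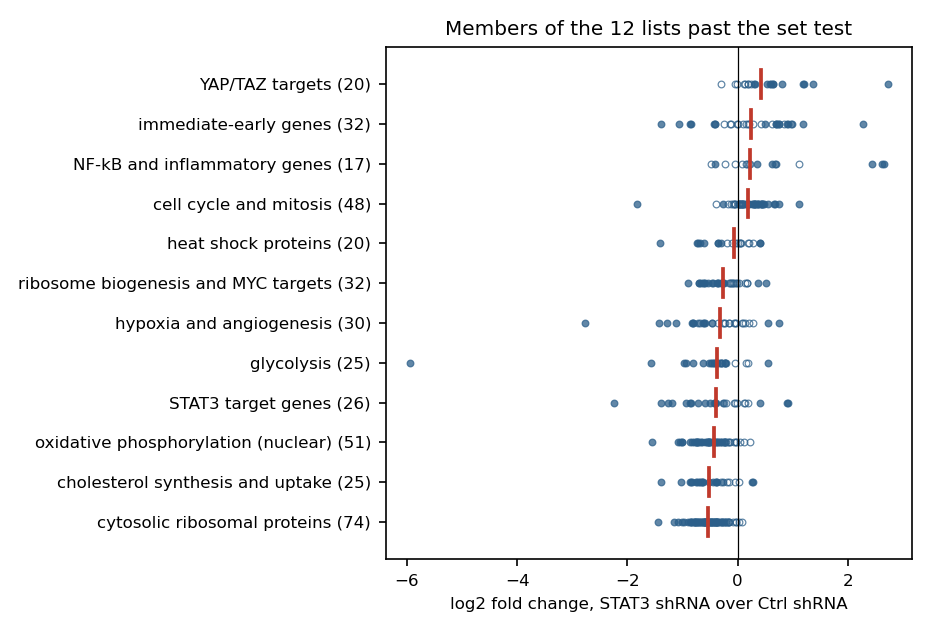
Log2 fold change (horizontal axis, STAT3 shRNA over Ctrl shRNA) of each tested member of the 12 lists past the camera test with the preset correlation; the number of members is in brackets, filled points passed an adjusted p under 0.05, open points did not, and red bars mark medians. Medians ran from -0.53 for cytosolic ribosomal proteins to 0.43 for YAP/TAZ targets.

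The other 28 lists did not pass the set test, and 24 of them held at least 3 changed members, where 35.5% of all tested genes changed. Counts were the same when adjusted over the list alone unless given. In the IL-6 and JAK-STAT pathway 6 genes rose and 5 fell of 36. The feedback inhibitor SOCS3 fell by 1.39 on the log2 scale, and PIAS1 and the interferon receptor chain IFNAR2 rose by 0.77 and 0.65. Interferon response genes had 11 higher and 8 lower of 44, with IFITM1, OASL and IFITM3 at -1.60, -1.25 and -1.12. Acute-phase proteins had 2 higher and 3 lower of 8, with complement C3 at -0.84, C4BPA at -2.62 and C4BPB at -0.59, and anti-apoptotic genes 3 higher and 5 lower of 12 (5 and 6 adjusted over the list alone), with BCL2L2 at -0.77, BIRC3 at 0.70 and CFLAR, in the lower segment of chromosome 2, at -0.57. Among p53 targets and apoptosis genes 9 rose and 3 fell of 34, led by the stress cytokine GDF15 (1.45), BCL2L11 (1.21) and BTG2 (0.75). ATF4 and amino acid response genes had 8 higher and 11 lower of 33, with GDF15 up and DDIT4 and TRIB3 down (TRIB3 at -0.88). In the unfolded protein response 9 rose and 2 fell of 24, with HERPUD1 at 0.73, EIF2AK3 at 0.59 and SEC61B at -0.69.

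Metabolic lists outside the called ones moved in both directions. NRF2 and oxidative stress genes had 6 higher and 12 lower of 32 (6 and 13 adjusted over the list alone), with ferritin heavy chain FTH1 at 0.98 on the log2 scale. AKR1C1 was at -4.26 alone, but its near-identical relative AKR1C2 was higher, and their sum had a log2 fold change of -0.06 (adjusted p = 0.681, edgeR), so the fall of AKR1C1 is uncertain. Ferroptosis and iron handling had 7 higher and 9 lower of 26 (8 and 9 adjusted over the list alone), with PTGS2 and FTH1 up and BMP6 at -1.31. Fatty acid oxidation and ketogenesis had 5 higher and 11 lower of 31, with ECI1 at -0.83, ACSL1 at -1.11 and ACSL3, in the lower segment of chromosome 2, at -0.65. Fatty acid synthesis and storage had 4 higher and 9 lower of 24, with stearoyl-CoA desaturase SCD, fatty acid synthase FASN and their regulator SREBF1 at -0.70, -0.70 and -0.66. Gluconeogenesis and glycogen genes had 3 higher and 4 lower of 15 (3 and 6 adjusted over the list alone), with IGFBP1 at 3.27, PPARGC1A at 1.09 and pyruvate carboxylase PC at -0.55. Autophagy and lysosome genes had 5 higher and 10 lower of 35 (5 and 11 adjusted over the list alone), with GABARAPL1 at -0.81 and ATG9A and ATG16L1, both in the lower segment of chromosome 2, at -0.87 and -0.93. Of 13 mitochondrially encoded genes 7 rose and 1 fell, with MT-CO2 at 0.53, MT-CO1 at 0.39 and MT-CYB at 0.41, and mitochondrial reads were 2.97% and 2.76% of the Ctrl shRNA and 3.94% and 3.63% of the STAT3 shRNA libraries. The calls of MT-CO1 and MT-CYB were lost without STAT3 shRNA replicate 1 (adjusted p = 0.0826 and 0.085; highest over all alternatives 0.242 and 0.0893). DNA replication genes had 6 higher and 2 lower of 36, with PRIM1 at 0.55 and MCM6 at 0.33. MCM6 lost its call without either STAT3 shRNA library (0.131 and 0.128), with a highest adjusted p of 0.131 over its alternatives.

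Lists of liver and epithelial genes were mixed too. Liver transcription factors had 7 higher and 3 lower of 16, with TBX3 at -1.10, and NR5A2 had 0 reads in the Ctrl shRNA libraries against 2.20 CPM, at least 27.9-fold higher (20.6-fold without STAT3 shRNA replicate 1). Wnt/beta-catenin targets had 5 higher and 3 lower of 14 (6 and 3 adjusted over the list alone), including LGR4 at 0.72 and RNF43 at 4.94 (5.86 without Ctrl shRNA replicate 2), the latter inside a span shared with SUPT4H1. Hepatoblast and fetal liver genes had 5 higher and 2 lower of 9, with PEG10 at 1.12 and the imprinted RNA H19 down from 9853 ± 2777 to 2782 ± 116.4 CPM (SD, n = 2 each). Bile acid synthesis and transport had 1 higher and 4 lower of 11, with SLCO1B3 at 1.81, FGFR4 at -1.19 and SLC27A5 at -1.44. Cytochrome P450 and drug metabolism genes had 4 higher and 3 lower of 14, with ABCG2 at -1.31, POR at -0.80, and CYP3A7 at 0 reads against 1.71 CPM, at least 21.6-fold higher. Epithelial junction genes had 6 higher and 5 lower of 24 (7 and 6 adjusted over the list alone), with CLDN1 up 4.01-fold, EPCAM at 1.84 and CLDN7 at -1.55. Epithelial-mesenchymal transition and matrix genes had 9 higher and 10 lower of 32 (9 and 11 adjusted over the list alone), with TGM2 at -1.50, COL4A1 at -0.94 and FN1, in the lower segment of chromosome 2, at -3.59. The remaining lists were hepatocyte secreted proteins (1 higher and 1 lower of 8), metallothioneins and zinc transport (0 and 2 of 7), replication-dependent histones (1 and 0 of 11) and RNA interference machinery (0 and 1 of 14), of which the last 2 had no member past the threshold when adjusted over the list alone. The median, mean and test differed in sign for 7 lists: p53 targets and apoptosis, fibroblast and stellate cell markers, gluconeogenesis and glycogen, cholangiocyte markers, hepatocyte secreted proteins, cytochrome P450 and drug metabolism, and replication-dependent histones.

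The fibroblast and cholangiocyte lists did not pass the set test, and the endothelial and immune lists had too few tested members for it. Fibroblast and stellate cell markers had 2 higher and 2 lower of 8, with COL1A1 at -1.47, MFAP5 at 0.85, and FAP, in the lower segment of chromosome 2, at 0 reads against 0.814 CPM in Ctrl shRNA, at least 12.2-fold lower (7.96-fold without Ctrl shRNA replicate 2). The 2 most abundant were FBLN1 (607.9 and 644.6 CPM in Ctrl and STAT3 shRNA) and COL1A1 (40.6 and 14.7 CPM). Cholangiocyte markers had 3 higher and 2 lower of 8 (4 and 2 adjusted over the list alone), with KRT7 at 1116 and 714.0 CPM and KRT19 at 107.3 and 161.0 CPM. Of 15 endothelial markers 4 were tested, the most abundant being EGFL7 (33.1 and 24.1 CPM) and ENG (1.37 and 26.7 CPM, a rise of 4.28 on the log2 scale). EGFL7 did not pass with all 4 libraries (adjusted p = 0.0967) but did in 3 alternatives, among them without Ctrl shRNA replicate 1 (2.55e-05) and with no low-count filter (range over its alternatives 2.55e-05 to 0.709). Of 18 immune markers 1 was tested, CD68, at 12.4 and 25.96 CPM, whose log2 fold change of 1.06 became 0.31 with the reads of the overlapping locus AC016876.2.

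Most secreted hepatocyte proteins were near the detection limit in all 4 libraries. Of 38 hepatocyte secreted proteins 23 were listed in the table and 8 passed the low-count filter, and the median of those listed was 0.0723 CPM. Of 27 acute-phase proteins 19 were listed and 8 passed, with a median of 0.133 CPM. Other liver lists held more abundant members: 7 of 14 listed hepatoblast and fetal liver genes reached 10 CPM (median 19.8 CPM), as did 8 of 23 of bile acid synthesis and transport and 8 of 33 of cytochrome P450 and drug metabolism (medians 0.275 and 0.250 CPM). Albumin (ALB) had 0, 0, 0 and 3 reads, APOA1 0, 0, 1 and 2 reads, and APOA2 0 reads in each library. Vitronectin (VTN) was at 13.9 CPM and the hepatocyte transcription factor HNF4A at 1.27 and 1.78 CPM in Ctrl shRNA and 7.20 and 4.95 CPM in STAT3 shRNA. These 5 genes were chosen after their values were seen. Members that the table does not list were not analysed here.

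Fold changes were also laid out along the chromosomes, with positions from GENCODE 29. On chromosome 2, 44 of the 77 tested genes that start below 25 Mb rose and 1 fell, with a median log2 fold change of 0.51. From 150 Mb to the end of the long arm 207 of 354 genes fell and 11 rose, with a median of -0.50, and the median reached -0.84 for the 89 genes beyond 225 Mb. Between 75 and 100 Mb the median was 0.02. Within a group the same genes hardly differed, with medians between replicates of -0.13 to 0.08 for each stretch of 25 Mb. A run of 50 genes on chromosome 1, from FBXO2 to ARHGEF10L (11637018 to 17697874), had 33 lower and 2 higher. Without a GC offset, runs of 50 genes also passed the 95th percentile of shuffled orders downward on chromosomes 8, 9, 11, 16 and 19 and upward on chromosomes 1, 10, 11 and 14. The lowest of these was on chromosome 16 (METRN to E4F1), with a median of -0.50, 29 lower and 1 higher. With the GC offset the runs that passed were on chromosome 2 and on chromosome 1 (lowest from FBXO2 to ARHGEF10L), with upward runs on chromosome 1 (AC096677.1 to SLC45A3) and chromosome 7. The upward runs on chromosomes 1 and 7 were marginal, with medians of 0.343 and 0.306 less that of all genes. The 95th percentile of shuffled orders was 0.302 and the highest shuffle 0.455. The 14718 genes outside the chromosome 2 segments and the FBXO2 to ARHGEF10L run had 2495 higher and 2603 lower and a median of 0.03. Named genes in the chromosome 2 segments are marked as such where they appear.

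**Figure D3:**
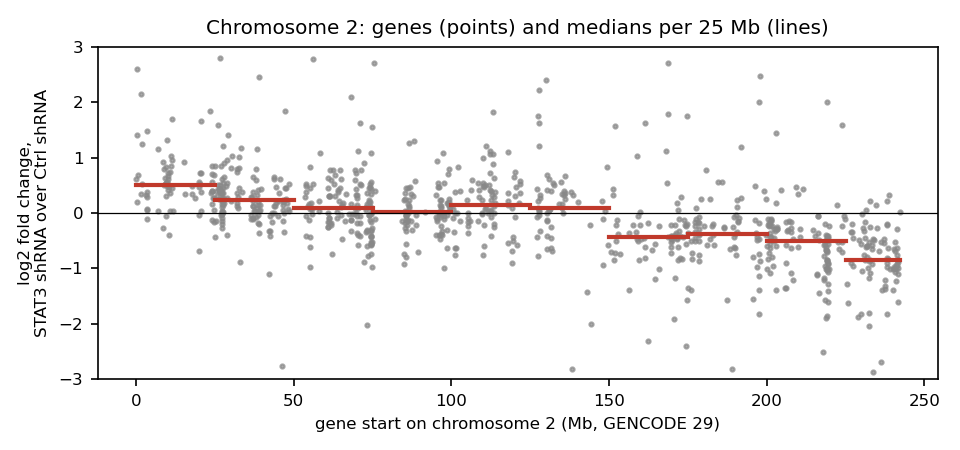
Log2 fold change (vertical axis, STAT3 shRNA over Ctrl shRNA) of tested genes against their start on chromosome 2 (horizontal axis, Mb, GENCODE 29); points are genes, red lines medians of 25 Mb, and 13 genes beyond 3 in size are not drawn. Medians were 0.51 below 25 Mb and -0.84 beyond 225 Mb.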

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

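STAT3 kept its direction and its call under every alternative run for it, with log2 fold changes from -2.85 to -2.32. Counts of changed genes lay within 1.5 times of 2552 higher and 2844 lower with RLE or upper-quartile scaling, either low-count filter, the edgeR exact test, and the length and GC offsets, which were added after the data were seen. Similar counts did not mean the same genes. With the GC offset 1991 of the 2552 higher and 2204 of the 2844 lower genes were called again. With the length offset 2236 and 2649 were. Upper-quartile scaling turned the balance, with 2949 higher and 2412 lower. Leaving out 1 library gave 1185 to 3426 genes higher and 1495 to 3891 lower, STAT3 at -2.82 to -2.76, 7 to 8 lists lower and 4 higher. The lone library was then assumed to vary like the other group, whose spread differed. Of the calls, 1169 to 2384 higher and 1446 to 2781 lower genes were the same ones. DESeq2 called 1630 higher and 2428 lower; it gave no adjusted p to 9527 genes with a p-value. On FPKM 1349 were higher and 1186 lower with a pseudocount of 1, and 1315 and 1179 with 0.1; the cause was not tested. A threshold of 0.01 left 1265 higher and 1632 lower, and a test against a fold of 1.5 left 527 and 472, both stricter by construction. None of the alternatives fitted to all genes called a gene in the opposite direction, but PWP2 was called lower with its copy summed (adjusted p = 0.000696). With an estimated correlation camera called 0 lists lower and 0 higher, and fry 0 and 2. All 12 lists kept their call with RLE, no filter and the GC offset; the length offset, upper-quartile scaling and the stricter filter lost heat shock proteins, the stricter filter also immediate-early genes, and the length offset added mitochondrially encoded genes.

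Samples with the same replicate number did not deviate together (correlation -0.0286 over 2 pairs). A replicate block gave 2594 higher and 2853 lower genes, STAT3 at -2.79, 7 lists lower and 5 higher, and EGFL7 passed with it.

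Of single named genes, FBLN1 changed sign without Ctrl shRNA replicate 1 (-0.049; 0.20 without replicate 2, then called) and with FPKM (-0.028 and -0.028), STAT5B without Ctrl shRNA replicate 2 (0.0032) and with FPKM (0.016 and 0.017), STAT5A with the GC offset (0.055) and with FPKM (0.085 and 0.089), and AHSA1 with FPKM (0.0017 and 0.0017). Only AHSA1 among these was called in counts, and the cause was not tested. Summing near-identical copies turned PWP2 to -0.66 and EIF3CL to -0.16. Over all alternatives 1877 single-gene values kept direction and call, 41 lost the call, 7 gained one and 13 changed sign. At this depth a 1.5-fold change was recovered in 23 of 50 simulated genes, so an unchanged call does not exclude changes of that size.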

Other observations

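Tests of the hepatocyte genes and of chromosome 2 alone, and the length and GC offsets, were chosen after the result was seen; a test of genes at 0 in one group was dropped before it was run, because its counts were already known.

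Some members of the tissue identity lists were abundant, while other members of some of the same lists were near the floor. In the squamous list, which holds TRIM29 and SFN, KRT5 was at 0 and KRT14 at 0.0133 CPM. Of its 9 genes with values 4 reached 1 CPM, and the median was 0.195 CPM. VIM was at 879.5 CPM, TRIM29 at 360.4 CPM, SFN at 292.7 CPM, the homeobox genes HOXA13 and HOXA11 at 84.7 and 70.0 CPM, FBN1 at 90.1 CPM and FOXA1 at 43.0 CPM, as means over the 4 libraries. Placental alkaline phosphatase (ALPP) was at 5100 CPM in Ctrl shRNA. Genes were picked from identity lists of 14 tissues after their values were seen. The median of the lists other than the hepatocyte list ran from 0.0613 CPM (intestinal epithelium) to 16.7 CPM (mesenchymal genes). Genes with 0 reads in one library and at least 20 in the other numbered 47 and 55 within the groups and 88 to 153 between them.

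Most hepatocyte identity genes were near the floor in all 4 libraries, which is surprising for a hepatoma line. VTN, CEBPA, HNF4A and TF were nonetheless at 13.9, 8.72, 3.80 and 1.37 CPM. Hepatoblast and fetal liver genes had a median of 19.8 CPM, but over only 14 of the 20 genes, 7 of which reached 10 CPM. That median is no measure of the hepatocyte identity genes. Of 20 hepatocyte identity genes, 11 were listed in the table, with a median of 0.171 CPM. Depth was not the limit, since 12742 genes reached 1 CPM in all 4 libraries, and the STAT3 hairpin was not either, since the median in Ctrl shRNA was 0.0265 CPM. Of 13 identity lists of other tissues 11 had a higher median, and 5 had a median of 1 CPM or more. The rule that most lists reach 1 CPM was reworded after these values were seen. Cells of a single other tissue need not raise most lists either, so these counts decide nothing. The other hepatocyte genes were not analysed here. Cells other than a hepatocyte-like line cannot be told apart from a line that lost these genes. No genotype was at hand to separate them.

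Ribosomal protein and oxidative phosphorylation genes fell together, while log2 fold changes also followed length and GC content across genes. With a length offset the ribosomal protein median was -0.42 and with a GC offset -0.51, and both lists kept their camera call (adjusted p of 6.6e-09 or less), so neither trend accounts for the whole fall. These calls assume a correlation of 0.01 among members and the random lists none, whereas it was estimated at 0.797 and 0.453. With an estimated correlation neither list passed (adjusted p = 0.666, camera). That form of the test cannot decide this, since it called 0 of 5 simulated lists that were shifted. It also gave 0.666 to the NF-kB and inflammatory list, whose correlation was estimated at -0.0145. Of 10000 random lists matched on expression and length, the median was -0.21, 2.5% lay under -0.30 and 0 lay at or under the ribosomal protein median of -0.53; for oxidative phosphorylation (median -0.43) the values were -0.22, -0.36 and 15, so matched genes share a part of both falls. Lower expression of both sets with STAT3 shRNA therefore stays open as a hypothesis. So do clone differences between the cells of the 2 groups, which the labels do not describe and which were not tested for these lists. The chromosome 2 segments and the FBXO2 to ARHGEF10L run hold 2 of the 74 ribosomal protein genes and 4 of the 51 oxidative phosphorylation genes. These segments alone therefore do not account for the 60 and 38 lower members.

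Neighbouring genes changed together, most of all on chromosome 2. The largest median of 50 consecutive genes, less that of all genes, was 0.90 in size (DIS3L2 to MTERF4, 231961245 to 241102332), against a 95th percentile of 0.35 in shuffled orders. GC content was not the whole cause: with a GC offset the value was 0.80 against 0.30, and the highest shuffle reached 0.46. Copy-number differences between the 2 groups of cells cannot be told apart genome-wide from other regional effects, because replicates also passed their shuffles. Without a GC offset this was the Ctrl shRNA pair (0.264 against 0.174). With a GC offset that pair no longer passed (0.137 against 0.144), but the STAT3 shRNA pair narrowly did (0.103 against 0.102). On chromosome 2 with a GC offset the value of 0.80 stood against at most 0.08 between replicates. Copy-number differences between the groups at the short-arm end and along the long arm may explain it. Fold changes cannot tell a short-arm gain with a long-arm loss in the STAT3 shRNA cells from the reverse in the Ctrl shRNA cells. The 207 genes that fell on the long arm may then owe nothing to STAT3. Regional silencing was not tested.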
